A study of Homo sapiens with 12 samples.

How the data were processed

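The samples came from MonoMac6 (MM6), an established human acute myeloid leukemia (AML) cell line of monocytic type. The cells carried a control short hairpin RNA (shNS) or 1 of 2 hairpins against IGF2BP2, an RNA-binding protein that reads m6A-modified transcripts (shBP2-1 and shBP2-2). Per the labels, lentivirus was applied for 48 h and puromycin selection lasted 2 days. Cells of each sample were taken for total RNA and a stranded mRNA library, and others for ribosome profiling, in which cycloheximide for 15 min held ribosomes on their transcripts and the RNA fragments protected by ribosomes (footprints) were sequenced after ribosomal RNA depletion with a small-RNA library kit. Each of the 6 groups of hairpin and assay held 2 replicates, which made 12 libraries. Whether the replicates were separate cultures is not given in the sources used here, and they may be technical.

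The deposited values were a score per gene and library, which the authors described as a normalized read count and rounded to whole numbers. The normalization method is not given in the sources used here. The submitters listed FastQC, cutadapt, Bowtie, STAR and RSEM with the human genome build hg38, without versions or the role of each. In 9 of the 12 libraries the low values skipped or doubled whole numbers at regular steps, as when read counts are multiplied by 1 factor per library and rounded, so the values were treated as scaled counts and not as counts. The table held 19951 gene entries named by symbol, of which 19187 symbols were in the reference name tables. Another 26 symbols occurred on 2 entries each, 578 entries had clone names, and 117 had names of readthrough transcripts that span neighbouring genes.

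The values of a library summed to between 22685066 and 24854593 for mRNA and to between 456338 and 4884067 for footprints. The planned test was limma with a mean-variance trend on log2(value + 1), two-sided, with 1 mean per group and 1 shared spread. Genes with a mean value of at least 10 over the libraries of an assay were tested, and calls had a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Within each assay the mean of both IGF2BP2 hairpins, each hairpin alone, and the difference between the hairpins were compared. The mRNA and footprint fits had 3 residual degrees of freedom each. Translational efficiency was the footprint change minus the mRNA change, tested as an interaction over all 12 libraries with 6 residual degrees of freedom, in genes that passed the minimum in both assays.

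Footprint totals differed about 10-fold between groups, so a further fit was chosen after the values were seen. Libraries were rescaled by median-ratio factors within each assay and tested with limma voom precision weights. Changes from that fit are called relative, since they compare each gene with the middle of all genes and not with an absolute amount. Median-ratio rescaling with the trend test, an alternative fixed earlier, called 442 genes for footprints and 2907 for translational efficiency in the mean of both hairpins, beside 860 and 3355 relative changes with weights.

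The comparisons, the alternatives, the gene lists and the rule for naming genes were fixed before the data were examined. The 29 lists covered the IGF2BP family, the m6A machinery, glutamine metabolism, the TCA cycle, nuclear OXPHOS genes, mtDNA-encoded genes, glycolysis, serine and one-carbon metabolism, cholesterol synthesis, ribosomal proteins, translation factors, the mitochondrial ribosome, MYC and MYC-responsive genes, the ATF4 stress response, the unfolded protein response, p53 targets, the BCL2 family, the interferon response, NFkB inflammatory genes, G1/S and G2/M cell cycle genes, AML self-renewal, myeloid differentiation, replication histones, lysosome and autophagy, and markers of T and NK cells, B cells, erythroid and megakaryocyte cells, and epithelial cells and fibroblasts. Lists with at least 3 tested genes were tested with limma camera at a preset correlation of 0.01 between genes, adjusted over the lists. The estimated correlation of each list and fry served as alternatives. With an estimated correlation camera also bases its test on the few residual degrees of freedom of the fit. These were 3 for mRNA and for footprints and 6 for translational efficiency. A call lost under that alternative therefore need not mean that the members of a list vary together.

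The rule named a fixed set of genes in each assay, of which IGF2BP2, IGF2BP1, IGF2BP3, MYC, GPT2, SLC1A5 and GLUL are reported, then the 10 called genes per direction with the largest change of the same sign in both hairpins, then the 4 members with the smallest p of each list called by camera. Lists called only through their members' own tests were left out of that last part, and for footprints and translational efficiency it used relative changes. Symbols on more than 1 entry and clone names were left out. Because the largest changes were mostly in genes with few reads or with reads shared between similar genes, a further selection was made after the values were seen. It took up to 10 called genes per direction with mean values of at least 500 in mRNA and 100 in footprints and no readthrough name. Gene coordinates are those of GRCh38.p14.

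Both hairpins were compared with the same shNS libraries, so their changes share error. The correlation and covariance expected from that alone came from 100 simulations of unchanged groups. A fold against a group at 0 in every library was computed with a floor of 3 per library and is given as a lower bound. Alternatives included pseudocounts of 0.1 and 5, no filter, a minimum mean of 50, median-ratio and quantile scaling, no trend, and leaving out each library in turn, where the remaining library of a group was assumed to vary like the others. Alternatives for the relative changes were added after the data were seen. Among them were footprints thinned to the smallest library and the shBP2-1 footprint libraries averaged as 1 sample, because those libraries differed by no more than counting noise (chi-square per degree of freedom 0.961 over 5807 genes).

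The fits were tested on simulated data with known changes. The mRNA fit recovered 88.1% of 1.5-fold and 98.5% of 2-fold changes, and 2.55% of its calls were unchanged genes. The relative footprint fit recovered 48.5% and 80% of them with 7.55% unchanged genes among its calls, and the relative efficiency fit recovered 50.8% and 77.4% with 3.97%. The simulated footprints had little spread beyond counting noise (dispersion 0.00013). The real shNS and shBP2-2 footprint pairs varied more (chi-square per degree of freedom 3.37 and 1.85). The mRNA simulation used 1 spread (dispersion 0.00503) for all groups, where real pairs ranged from 2.88 to 21.2. These rates may therefore not hold for the real data. The list test called the 1 list shifted by 1.5-fold and 0 of the unshifted lists. Simulated genes were independent, so this could not test the preset correlation where members of a real list vary together. In the real mRNA values the estimated correlation was 0.245 for glycolysis and 0.9545 for mtDNA-encoded genes. The tools were R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.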

Results

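The data covered mRNA and ribosome footprints in MM6 cells with a control hairpin (shNS) or with either of 2 hairpins against IGF2BP2 (shBP2-1 and shBP2-2), with 2 libraries per group. The series concerns how IGF2BP2, a reader of m6A-modified RNA, acts on glutamine metabolism in AML. The mRNA values summed to 22685066 and 22870251 in shNS, 23764161 and 24854593 in shBP2-1, and 23506946 and 23116887 in shBP2-2. Footprint values summed to 4884067 and 4423843 in shNS, 504631 and 456338 in shBP2-1, and 1686279 and 2583384 in shBP2-2. The mean footprint total was thus 9.69-fold below shNS with shBP2-1 and 2.18-fold below it with shBP2-2, while mRNA totals were nearly equal. These are totals of scaled values. The factors estimated for the mRNA libraries ran from 0.7125 to 1.4365, so nearly equal mRNA totals do not show equal mRNA amounts. Error values after ± are the standard error (SE) of a log2 fold change unless marked SD, and each group had n = 2. For the mean of both hairpins the SE and p come from the spread between libraries within groups. They leave out the difference between the hairpins, so they do not measure how well an effect repeats across hairpins.

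IGF2BP2 was knocked down by both hairpins. Its mRNA (chromosome 3, 185643130 to 185825042) averaged a normalized read count of 2414 ± 80.6 (SD, n = 2) in shNS, 492 ± 21.2 in shBP2-1 and 735 ± 52.3 in shBP2-2, which left 20.4% and 30.5% of the control level. In limma the mean of both hairpins gave a log2 fold change of -2.0 ± 0.09 (adjusted p = 4.11e-07), lower in 4 of 4 knockdown libraries. Its footprints went from 575 and 526 in shNS to 2 and 4 in shBP2-1 and to 20 and 33 in shBP2-2, or to 5.57% and 10.7% of shNS once the libraries were rescaled. The paralog IGF2BP1 had mRNA values of 0 or 1 in all libraries and no footprints. IGF2BP3, the third family member, was low and rose from 19.5 ± 3.54 (SD) to 48.0 ± 4.24 in shBP2-1 and 41.5 ± 4.95 in shBP2-2 (log2 fold change 1.16 ± 0.24, adjusted p = 0.00262, or 0.195 in a fit over all 12 libraries), with at most 4 footprints in any library.

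**Figure D1:**
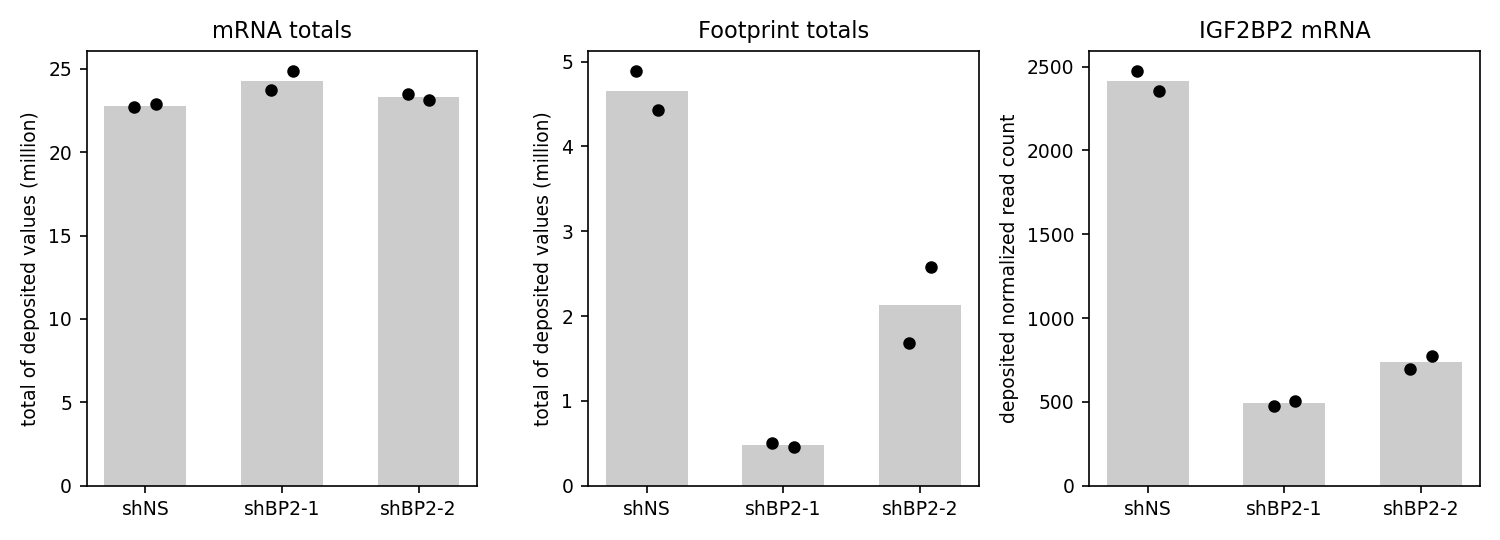
Summed mRNA values, summed footprint values and the IGF2BP2 mRNA value (normalized read count) per group, with bars for the mean and points for the 2 libraries. Footprint totals were 9.69-fold and 2.18-fold below shNS with shBP2-1 and shBP2-2, and IGF2BP2 mRNA kept 20.4% and 30.5% of its control level.

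The mRNA comparison asked which transcripts depend on IGF2BP2, and transcripts of glutamine use were among those that fell. GPT2, the mitochondrial alanine transaminase (chromosome 16, 46884362 to 46931289), fell from a mean of 1322 in shNS to 405 and 729, a log2 fold change of -1.29 ± 0.11 (adjusted p = 3.17e-05). SLC1A5, the main glutamine importer (chromosome 19, 46774883 to 46788594), fell from 11440 to 4794 and 6746 (-1.02 ± 0.10, adjusted p = 0.000102). MYC, a transcription factor that drives growth and glutamine use (chromosome 8, 127735434 to 127742951), fell from 12480 to 7734 and 8406 (-0.63 ± 0.08, adjusted p = 0.000389). All 3 were lower in 4 of 4 knockdown libraries than in either shNS library. The glutamine synthetase gene GLUL fell slightly (-0.22 ± 0.07, adjusted p = 0.0214). This small change lost its call without shBP2-2 replicate 1 (adjusted p = 0.085), shBP2-2 replicate 2 (0.057), shNS replicate 1 (0.20) or shNS replicate 2 (0.16). In a fit over all 12 libraries, which shares the spread with footprints, SLC1A5 kept its call (adjusted p = 0.0288) and GPT2 (0.0895), MYC (0.129) and GLUL (0.412) lost theirs.

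Across 12203 tested genes, limma called 3460 higher and 3669 lower in the mean of both hairpins, with a median log2 fold change of -0.02. The call count fell to 2768 without shNS replicate 1 and to 4154 without shNS replicate 2, and the fit over all 12 libraries left 36 higher and 53 lower (2736 genes at unadjusted p under 0.05). Of the genes named in this paragraph that fit ended the calls of G0S2, ABCA8, SEMA3C, GDF1, MICOS10-NBL1, ZNF816-ZNF321P and POC1B-GALNT4. The largest decreases included the glutathione-degrading enzyme gene CHAC1 (-3.62 ± 0.15, adjusted p = 4.11e-07), the glycine transporter gene SLC6A9 (-3.95 ± 0.28), INHBE (-3.13), ADM2 (-3.03) and the stress cytokine gene GDF15 (-2.67 ± 0.38). The potassium channel gene KCNG1 (-2.88) and the lipolysis inhibitor gene G0S2 (-2.51) also fell. Values in shNS were low already for INHBE (80.5), GDF15 (68), G0S2 (37.5) and KCNG1 (29). The water and glycerol channel gene AQP9 had the largest increase among genes with names of their own and calls kept without any 1 library (2.24 ± 0.54, adjusted p = 0.00485), at low values of 2.5 in shNS, 25 in shBP2-1 and 8 in shBP2-2. SLITRK6 (2.52), ABCA8 (2.37) and SEMA3C (2.18) rose too, but SLITRK6 and SEMA3C lost their calls without shNS replicate 1 (adjusted p = 0.074 and 0.080) and ABCA8 without shNS replicate 2 (0.084). The remaining largest values belonged to genes with few reads or with sequence shared with a neighbour or paralog. C8orf44-SGK3, GDF1, MICOS10-NBL1 and KBTBD11-OT1 were at 0 in shNS and at least 19.5-fold, 18.1-fold, 8.58-fold and 6.33-fold higher in the mean of the knockdown libraries. Their replicates were uneven: GDF1 had 0 and 76 in shBP2-2, MICOS10-NBL1 0 and 35 in shBP2-1, and C8orf44-SGK3 12 and 125 in shBP2-1. UTP14C was at 0 in all 4 knockdown libraries and at least 68.3-fold lower, and H2AC18 (-4.63) and P3R3URF-PIK3R3 (4.55) also have close sequence relatives. ZNF816-ZNF321P (2.69) lost its call without shNS replicate 2 (adjusted p = 0.088) and POC1B-GALNT4 (-3.37) without shNS replicate 1 or 2 (0.080 and 0.18).

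Among abundant transcripts, chosen after their values were seen, the ecto-nucleotidase gene NT5E rose by 1.22 ± 0.10 on the log2 scale, the surface protein gene CD109 by 0.97 and the lipoprotein lipase gene LPL by 0.94. The endoplasmic reticulum chaperone gene HSP90B1 rose by 0.82, and C1GALT1C1 (1.00), SLC39A10 (0.99), CHD1 (0.92), NUCB2 (0.91), HSPA4L (0.86) and CHCHD7 (0.86) completed the group, of which HSP90B1, HSPA4L and CHCHD7 lost their calls in the fit over all 12 libraries (adjusted p = 0.0858, 0.0870 and 0.0775). The mitochondrial PEP carboxykinase gene PCK2 fell (-1.59 ± 0.10, adjusted p = 4.02e-06), as did the pseudokinase gene TRIB3 (-1.55), the translation repressor gene EIF4EBP1 (-1.37), the arginine synthesis gene ASS1 (-1.35), CARS1 (-1.31) and ATP5F1D (-1.30).

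Of the fixed lists, camera called 6 in mRNA, and 0 of these held with an estimated correlation, under which 3 lists had an unadjusted p below 0.05. That alternative also rests on 3 residual degrees of freedom. The estimated correlation was -0.049 for serine and one-carbon metabolism and -0.012 for glutamine metabolism, below the preset 0.01. The loss of these 2 calls thus does not come from members that vary together. Some genes were in several lists. This applied to 10 of the 40 genes written for the ATF4 stress response, 7 of 18 for serine and one-carbon metabolism and 6 of 30 for glutamine metabolism. The calls of these lists are thus not independent. Genes of the ATF4 stress response, which restores amino acid supply, were lower in 30 of 32 and higher in 0, with a median of -1.12 (adjusted p = 5.80e-18; adjusted p = 0.191 with an estimated correlation; 30 lower adjusted over the list alone). Examples were STC2 (-1.79 ± 0.08), DDIT4 (-1.79), ALDH1L2 (-1.81) and CHAC1. The serine and one-carbon list had 10 lower, 1 higher and 6 not past the threshold of 17 (median -0.54, adjusted p = 0.00111; adjusted p = 0.301 with an estimated correlation; 10 lower and 1 higher adjusted over the list alone), led by PHGDH (-1.61), SHMT2 (-1.08) and PSAT1 (-1.17). The glutamine metabolism list had 17 lower, 6 higher and 5 not past the threshold of 28 (median -0.45, adjusted p = 0.00619; adjusted p = 0.301 with an estimated correlation; 17 and 6 adjusted over the list alone), including ASNS (-1.03), SLC7A5 (-1.24) and GPT2.

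Ribosomal protein transcripts were lower in 57 of 79 and higher in 8, with a median of -0.38 (adjusted p = 1.48e-07; adjusted p = 0.530 with an estimated correlation; 59 lower and 8 higher adjusted over the list alone), as in RPL27A (-1.07), RPL13A (-0.76) and RPL13 (-0.64). Glycolysis transcripts were lower in 14 of 25 and higher in 2 (median -0.31, adjusted p = 0.0268; adjusted p = 0.631 with an estimated correlation; 15 and 2 adjusted over the list alone). The phosphofructokinase genes PFKL (-0.78) and PFKP (-0.65) and the aldolase gene ALDOA (-0.50) fell while the lactate dehydrogenase gene LDHA (0.45) rose. ALDOA and LDHA lost their calls without shNS replicate 1 (adjusted p = 0.050 and 0.051). Transcripts of the mitochondrial genome were higher in 7 of 13 and lower in 0 (median 0.34, adjusted p = 0.0215; adjusted p = 0.703 with an estimated correlation; 7 higher adjusted over the list alone), a call that quantile scaling ended (median 0.04, adjusted p = 0.24). MT-ND4L (0.67), MT-ATP8 (0.61) and MT-ND5 (0.54) led them, and MT-ATP6 (0.38) lost its call without shNS replicate 1 or 2 (adjusted p = 0.13 and 0.084). Of the genes named in this paragraph only RPL27A kept its call in the fit over all 12 libraries (adjusted p = 0.0108).

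The other lists were not called in mRNA, and counts of members called higher and lower follow each median. Growth-related lists were MYC and MYC-responsive genes (-0.28, 11 higher and 24 lower of 43, adjusted p = 0.0658), translation factors (-0.10, 13 and 16 of 45), the mitochondrial ribosome (-0.15, 21 and 31 of 77), G1/S genes (-0.02, 4 and 12 of 28) and G2/M genes (0.14, 11 and 4 of 30). Under quantile scaling the MYC list passed, with an adjusted p of 0.016. Metabolic lists were the TCA cycle (-0.07, 8 and 11 of 28), nuclear OXPHOS genes (-0.08, 17 and 33 of 77) and cholesterol synthesis (-0.27, 8 and 12 of 23). Stress and signalling lists were the unfolded protein response (0.06, 8 and 6 of 20), p53 targets (-0.22, 7 and 9 of 24), the BCL2 family (-0.28, 4 and 9 of 21), NFkB genes (-0.32, 6 and 14 of 25), the interferon response (0.25, 13 and 7 of 37) and lysosome and autophagy (-0.13, 4 and 6 of 25). Identity lists were myeloid differentiation (-0.07, 14 and 11 of 34, whose mean of 0.00 and upward test differed in sign from the median), AML self-renewal (0.08, 6 and 2 of 25), the m6A machinery (0.20, 9 and 2 of 20) and replication histones (-0.23, 0 and 2 of 7). Marker lists of other lineages had few tested genes: T and NK cells (-0.73, 0 and 3 of 3), B cells (-0.33, 0 and 0 of 3), epithelial cells and fibroblasts (-0.31, 1 and 1 of 5), and erythroid and megakaryocyte cells with 1 tested gene and no list test. The IGF2BP family had 2 tested genes, the fallen IGF2BP2 and the risen IGF2BP3, and no list test.

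Each hairpin was also compared with shNS alone and with the other. CHAC1, SLC6A9, STC2 and ASNS fell further with shBP2-1: CHAC1 was at -5.99 with shBP2-1 and -1.24 with shBP2-2 (difference -4.75, adjusted p = 7.5e-08), SLC6A9 at -6.28 and -1.61, STC2 at -3.05 and -0.54, and ASNS at -1.78 and -0.28. GPT2 and SLC1A5 followed the same order (-1.71 and -0.86; -1.26 and -0.77), whereas MYC changed alike (-0.69 and -0.57; difference -0.12, adjusted p = 0.36). RPL27A went the other way, at -0.23 with shBP2-1 and -1.91 with shBP2-2. With shBP2-1, limma called 2974 genes higher and 2369 lower, with shBP2-2 3170 and 3713, and 2981 genes differed between the hairpins. The shBP2-1 count was 3154 without its replicate 2, 1414 without shNS replicate 1 and 2480 without shNS replicate 2. The shBP2-2 count was 4443 without its replicate 1 and 3676 without shNS replicate 1, and the difference count was 1921 without shBP2-2 replicate 1. The fit over all 12 libraries left 71 calls for shBP2-1, 145 for shBP2-2 and 178 for the difference.

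**Figure D2:**
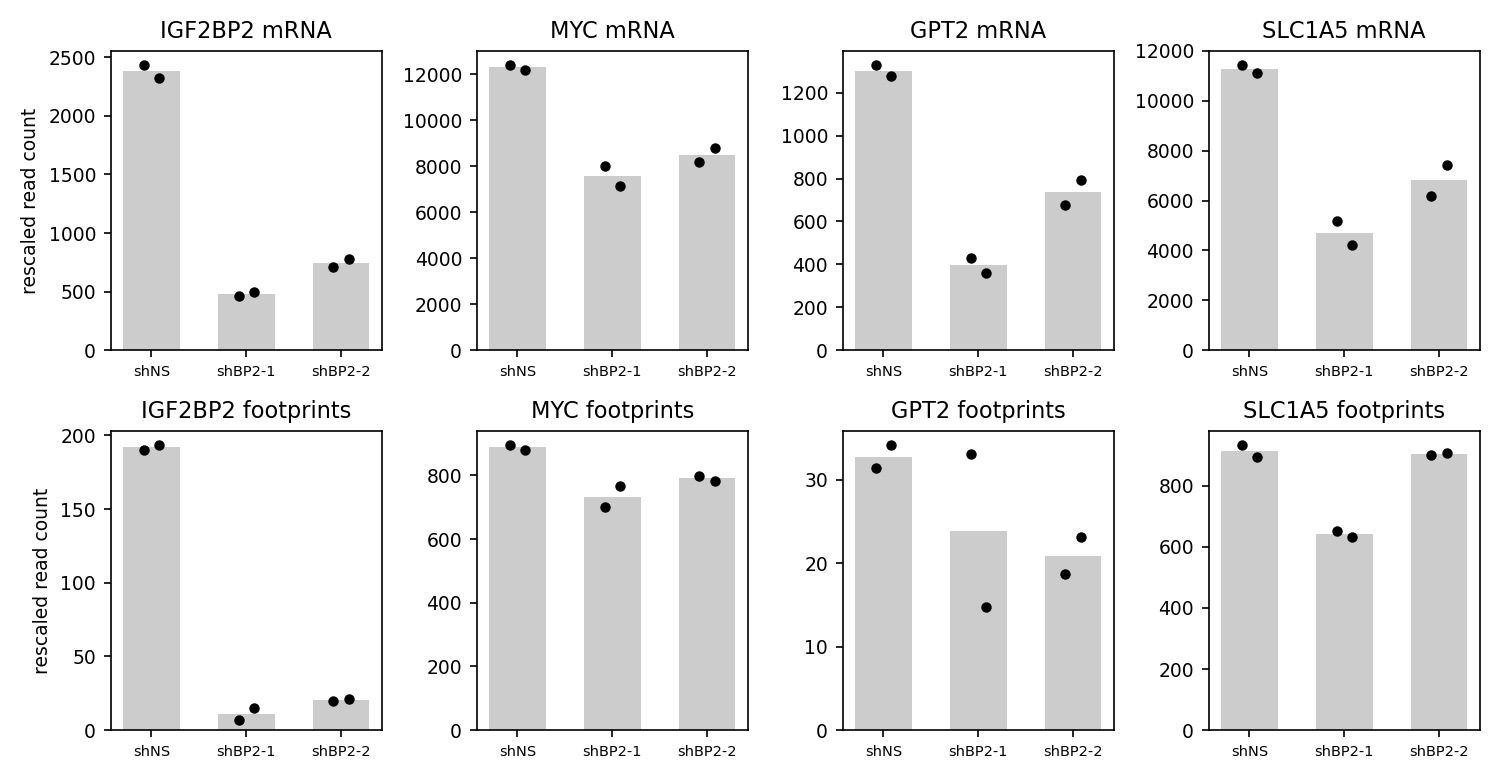
Rescaled normalized read counts of IGF2BP2, MYC, GPT2 and SLC1A5 in mRNA and in footprints per group, with bars for the mean and points for the 2 libraries. In mRNA all 4 genes were lower with both hairpins (log2 fold changes -2.0, -0.63, -1.29 and -1.02), while in footprints IGF2BP2 changed by -3.62 and the others by no more than -0.52.

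The footprint comparison asked which transcripts were translated less without IGF2BP2, and in the deposited values nearly all were lower. IGF2BP2 footprints had a log2 fold change of -5.76 ± 0.35, MYC -2.48, GPT2 -2.74, SLC1A5 -2.51 and GLUL -2.30, against a median of -2.23 over 9306 genes. limma called 9258 genes lower and 6 higher, and with shBP2-1 alone (median -3.27) 9281 and 2. With shBP2-2 alone (median -1.18) 7676 genes were lower and 20 higher, a count that was 166 in all without shNS replicate 1, 3600 without shNS replicate 2 and 4999 without shBP2-2 replicate 1. Furthest below that median lay CHAC1 (-4.25), RPL22 (-4.54), CBSL (-4.64), CBWD1 (-4.55), H4C12 (-8.10), H2AC19 (-5.76), SPECC1L-ADORA2A (-5.12) and RNASEK-C17orf49 (-4.17), and all but CHAC1 share sequence with relatives or neighbours. UBE2F-SCLY had no footprints in the knockdown and was at least 14.3-fold lower. SNRPD3 (1.79) and RPL36A-HNRNPH2 (2.23) were above shNS, but without shNS replicate 2 SNRPD3 lost its call (adjusted p = 0.051) and RPL36A-HNRNPH2 reversed to -0.53. Camera called 14 lists, 13 of them down, and p53 targets as up although their median was -2.0. None held with an estimated correlation (0 lists, and 0 at an unadjusted p below 0.05), and the call count was 3 and 2 without shBP2-1 replicate 1 and 2.

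Relative to the middle of all genes, IGF2BP2 footprints still fell by 3.62 ± 0.28 on the log2 scale (adjusted p = 1.5e-05). The asparagine synthetase gene ASNS fell (-1.47 ± 0.13, adjusted p = 3.71e-05), with the cystine importer gene SLC7A11 (-1.42 ± 0.15), CHAC1 (-2.33 ± 0.38) and the serine synthesis genes PSAT1 (-0.99 ± 0.08), PSPH (-1.34) and PHGDH (-0.76). GPT2 footprints were not called (-0.52 ± 0.26, adjusted p = 0.229), and neither were those of GLUL (-0.05, adjusted p = 0.685). The GPT2 value was -0.80 without shBP2-1 replicate 1 and -0.26 without shBP2-1 replicate 2. MYC (-0.22 ± 0.06, adjusted p = 0.0257) and SLC1A5 (-0.26 ± 0.06, adjusted p = 0.0136) fell slightly. The MYC call was lost without shBP2-1 replicate 1 or 2 (adjusted p = 0.26 and 0.12) or shBP2-2 replicate 1 or 2 (0.052 and 0.066), and that of SLC1A5 without shBP2-1 replicate 1 or 2 (0.12 and 0.14).

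Over all 9306 genes, 462 were higher and 398 lower in these relative footprint changes, or 221 and 221 by median-ratio rescaling without weights. The count was 254 and 271 without shBP2-1 replicate 1 and 2, and 538 without shBP2-2 replicate 1. The proliferation factor gene PCLAF (2.93 ± 0.58) led the increases among genes with unshared names, but with 22 and 3 footprints in shNS it was at 4.26 without shNS replicate 1 and 1.73 without shNS replicate 2. It was followed by ABCB6 (2.11), ABHD4 (1.91) and TP53INP2 (1.88), of which ABCB6 and ABHD4 lost their calls without shBP2-1 replicate 1 (adjusted p = 0.088 and 0.051) and TP53INP2 without shBP2-1 replicate 2 (0.053). SNRPD3 (4.04), ABHD14A-ACY1 (3.11) and MTRNR2L1 (2.03) rose, and RPL22 (-2.28 ± 0.16), H2AC19 (-4.01) and UBE2F-SCLY fell, in all of which reads shared between similar genes leave the assignment uncertain. Among abundant genes chosen after their values were seen, the cytoskeletal linker gene PLEC (1.17 ± 0.10), LY6E (0.97), EMC10 (0.94), DNPH1 (0.90) and LPL (0.85) rose with both hairpins. DDIT4 (-1.22 ± 0.14) and the chloride channel gene CLIC4 (-1.08) fell, as did STC2 (-1.44) and SMN1 (-1.27), whose calls ended without shBP2-1 replicate 1 (STC2, adjusted p = 0.050) and 2 (SMN1, 0.13).

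Camera called 11 lists in relative footprints, and only the ATF4 stress response held with an estimated correlation. That correlation was below the preset 0.01 for glycolysis (-0.020) and for serine and one-carbon metabolism (-0.036), so their lost calls do not come from members that vary together. ATF4 genes were lower in 23 of 31 and higher in 0 (median -0.63, adjusted p = 2.14e-22; adjusted p = 0.0340 with an estimated correlation; 25 lower adjusted over the list alone). The serine and one-carbon list had 6 lower and 0 higher of 16 (median -0.22, adjusted p = 0.000555; adjusted p = 0.205 with an estimated correlation; 8 lower and 1 higher adjusted over the list alone), with PSAT1, PHGDH and MTHFD2 (-0.63). Glycolysis genes had more footprints in 9 of 24 and fewer in 0 (median 0.18, adjusted p = 2.70e-05, or 0.170 with an estimated correlation). Adjusted over the list alone 12 were higher and 2 lower, led by ENO1 (0.28 ± 0.02), GAPDH (0.29) and LDHA (0.27). Quantile scaling brought this median to 0.096, with 6 higher (camera adjusted p = 0.00409). Lysosome and autophagy genes were higher in 10 of 22 and lower in 1 (median 0.17, adjusted p = 0.00156; adjusted p = 0.222 with an estimated correlation; 10 and 3 adjusted over the list alone), with the protease gene CTSD (0.61) and the autophagy receptor gene SQSTM1 (0.61). Myeloid differentiation genes were higher in 8 of 32 and lower in 1 (median 0.17, adjusted p = 0.000555; adjusted p = 0.269 with an estimated correlation; 12 and 1 adjusted over the list alone), in which S100A8 was at 1.19 with shBP2-1 and -0.15 with shBP2-2 (mean 0.52), LYZ at 0.71 and -0.25 (0.23) and the granule enzyme gene MPO at -0.07 and -1.37 (-0.72).

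In the mean of both hairpins, which averages a rise with shBP2-1 (median 1.03) and a fall with shBP2-2 (median -0.53), footprints of mitochondrial genome transcripts were higher in 6 of 13 and lower in 0 (median 0.31, adjusted p = 2.29e-05; adjusted p = 0.274 with an estimated correlation; 8 higher adjusted over the list alone), as in MT-ND5 (0.44) and MT-ND4 (0.41). Replication histones were lower in 6 of 14 (median -0.21, adjusted p = 0.00109; adjusted p = 0.274 with an estimated correlation; 6 lower adjusted over the list alone). H2AC11 (-0.42) and H2BC4 (-0.49) were examples, with calls that ended without shBP2-1 replicate 2 (H2AC11, adjusted p = 0.051) and 1 (H2BC4, 0.19). Unfolded protein response genes were higher in 7 of 20 and lower in 1 (median 0.09, adjusted p = 0.0264; adjusted p = 0.274 with an estimated correlation; 9 and 2 adjusted over the list alone), led by the chaperone genes HSPA5 (0.51) and HSP90B1 (0.28). Mitochondrial ribosome genes were lower in 8 of 77 and higher in 3 (median -0.10, adjusted p = 0.0264; adjusted p = 0.222 with an estimated correlation; 11 and 3 adjusted over the list alone), as in MRPL27 (-0.72). Nuclear OXPHOS genes were lower in 10 of 77 and higher in 2 (median -0.09, adjusted p = 0.0421; adjusted p = 0.269 with an estimated correlation; 15 and 7 adjusted over the list alone), as in UQCRB (-0.48) and CYCS (-0.44). Quantile scaling ended the last 3 of these list calls (adjusted p = 0.31, 0.066 and 0.066). G2/M genes had 1 member higher and 1 lower of 30 (median -0.10, adjusted p = 0.0200; adjusted p = 0.222 with an estimated correlation; 1 lower adjusted over the list alone), so that call rested on small changes of many genes.

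Among the 13 lists not called in relative footprints, glutamine metabolism came closest, with 7 lower, 4 higher and a median of -0.00 over 27 genes (adjusted p = 0.0588; adjusted p = 0.269 with an estimated correlation). Ribosomal proteins, whose lower mRNA was not called with an estimated correlation (adjusted p = 0.530), had 19 genes higher and 15 lower in footprints, with a median of -0.01 beside an upward test. The median, mean or test also differed in sign for cholesterol synthesis, translation factors, MYC-responsive genes, NFkB genes and AML self-renewal, all with medians between -0.03 and 0.03.

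Relative to the middle of all genes, mitochondrially encoded footprints went in opposite directions with the 2 hairpins. Their deposited sums were below shNS with both, 4.55-fold with shBP2-1 and 3.16-fold with shBP2-2. With shBP2-1 all 13 were higher (median 1.03, adjusted p = 1.42e-21; adjusted p = 0.15 with an estimated correlation), and with shBP2-2 10 of 13 were lower (median -0.53, adjusted p = 1.82e-08; adjusted p = 0.202 with an estimated correlation). MT-ND6 was at 1.41 and -0.58 (difference 1.99, adjusted p = 2.2e-07), and MT-ND4 at 1.36 and -0.53. ATF4 genes had medians of -1.09 with shBP2-1 and -0.29 with shBP2-2, and ASNS was at -2.19 and -0.75 (difference -1.45, adjusted p = 0.0044). Cholesterol synthesis genes had medians of -0.23 and 0.20, with 0 higher and 3 lower under shBP2-1 and 8 higher and 0 lower under shBP2-2. Camera called this difference between the hairpins and that of the ATF4 genes, but neither call held with an estimated correlation. SLC1A5 footprints fell with shBP2-1 (-0.51) and not with shBP2-2 (-0.02; difference -0.49, adjusted p = 0.0086), and those of the interferon receptor gene IFNAR1 were at 2.53 and 0.21 (difference 2.32, adjusted p = 1.3e-05). In relative footprints 359 genes were higher and 268 lower with shBP2-1, 653 and 495 with shBP2-2, and 583 differed between the hairpins. Median-ratio rescaling without weights turned the order of the hairpins around, with 607 higher and 878 lower for shBP2-1, 160 and 137 for shBP2-2 and 1849 differences. With the shBP2-1 libraries averaged as 1, the shBP2-1 and difference counts were 81 and 108. Without shBP2-1 replicate 1 or 2 the shBP2-1 count was 93 or 103 and the difference count 110 or 127. Without shBP2-2 replicate 1 or 2 the shBP2-2 count was 451 or 495 and the difference count 321 or 292, which became 898 or 893 without shNS replicate 1 or 2.

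**Figure D3:**
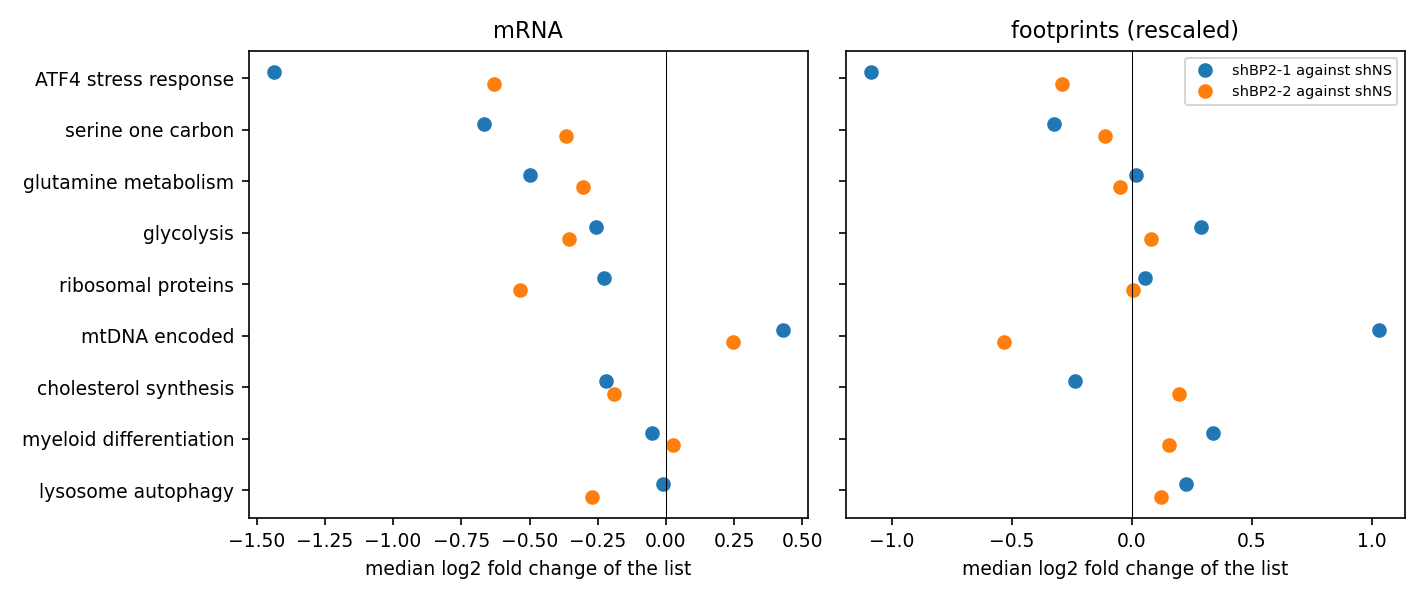
Median log2 fold change against shNS of 9 gene lists for shBP2-1 (blue) and shBP2-2 (orange), in mRNA on the left and in rescaled footprints on the right. ATF4 genes were lower with both hairpins in both assays (medians -1.44 and -0.63 in mRNA, -1.09 and -0.29 in footprints), and mitochondrially encoded footprints went apart (1.03 and -0.53).

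Translational efficiency, the footprint change over the mRNA change, asked whether ribosome occupancy moved beyond transcript amount. In the deposited values it was dominated by the footprint totals: IGF2BP2 was at -3.75 ± 0.34, MYC at -1.84, GPT2 at -1.45, SLC1A5 at -1.50 and GLUL at -2.08, against a median of -2.24 over 9216 genes. limma called 9092 genes lower and 5 higher, with 9175 and 2 for shBP2-1, 5735 and 10 for shBP2-2, and 8932 between the hairpins. The lowest were H4C12 (-8.02), MICOS10-NBL1 (-6.50), H2AC19 (-6.09), CBWD1 (-5.00), RPL22 (-4.67) and SMIM10 (-4.19), and the readthrough entries CHURC1-FNTB, BORCS8-MEF2B, HSPE1-MOB4 and COMMD3-BMI1 lay between -4.77 and -4.49. SNRPD3 (1.60) and ABHD14A-ACY1 (2.1) were higher, as was RPL36A-HNRNPH2 (3.94), which lost its call without shBP2-2 footprint replicate 1 (adjusted p = 0.059) or shNS footprint replicate 2 (0.12). Camera called OXPHOS, translation factor and G2/M genes as lower, and 0 lists with an estimated correlation or without shBP2-1 footprint replicate 1 or 2, where 3 lists had an unadjusted p below 0.05. The number was 8 and 9 lists without shBP2-2 footprint replicate 1 and 2.

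In relative efficiency IGF2BP2 fell (-1.63 ± 0.30, adjusted p = 0.000542), so its footprints dropped further than its mRNA. SLC1A5 rose (0.74 ± 0.12, adjusted p = 0.000175), as did MYC (0.39 ± 0.10, adjusted p = 0.00594) and GPT2 (0.76 ± 0.29, adjusted p = 0.0446), because their mRNA had fallen more than their footprints. GLUL was not called (0.16, adjusted p = 0.223). With 1 library left out GPT2 lay between 0.47 and 1.01. The MYC call ended without shNS mRNA replicate 1 (adjusted p = 0.060). GPT2 lost its call without shBP2-1 footprint replicate 1 (0.31), shBP2-2 footprint replicate 2 (0.095), shNS footprint replicate 1 (0.082), shBP2-1 mRNA replicate 2 (0.070), shBP2-2 mRNA replicate 1 (0.072) or shNS mRNA replicate 1 or 2 (0.093 and 0.063). Footprint minus mRNA per replicate number, with median ratios, takes same-numbered libraries as 1 culture, which the labels do not state. Under this block 0 of the 4 calls remained, with IGF2BP2 at -1.66 (adjusted p = 0.0537), SLC1A5 at 0.74 (0.0547), MYC at 0.39 (0.112) and GPT2 at 0.68 (0.126).

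In all, 1587 genes were higher and 1768 lower in relative efficiency, or 1248 and 1659 by median-ratio rescaling without weights, and the count was 2078 without shNS mRNA replicate 1. The block on footprint minus mRNA left 10 higher and 26 lower (3534 genes at unadjusted p under 0.05), and of the genes named in this paragraph only UBXN11 kept its call (adjusted p = 0.0432). The largest changes in genes with unshared names were the increases of PCLAF (3.14), TRAPPC5 (3.11), UBXN11 (2.34) and ABCB6 (2.27) and the decreases of COX20 (-2.41) and SMIM10 (-2.47), all with at most 39 footprints in any library. With 1 footprint library left out PCLAF lay between 1.94 and 4.47, TRAPPC5 between 2.28 and 3.93, COX20 between -3.70 and -1.49, and SMIM10 between -2.89 and -1.89. COX20 lost its call without shNS footprint replicate 2 (adjusted p = 0.090). Among abundant genes chosen after their values were seen, PLEC (1.28 ± 0.15), LY6E (1.29), DNPH1 (1.30), the lymphoid adaptor gene SASH3 (1.24) and the tryptase gene TPSAB1 (1.13) were higher. The complex III subunit gene UQCRB (-1.26 ± 0.13), CACYBP (-1.34), the G1/S cyclin gene CCNE2 (-1.23), the helicase gene DHX29 (-1.22) and FANCL (-1.19) were lower.

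Camera called 5 lists in relative efficiency, and 0 held with an estimated correlation, under which 4 had an unadjusted p below 0.05. Ribosomal proteins had a median of -0.01 in relative footprints, so their rise came from the mRNA change against shNS, and mRNA changes followed a component that also separates replicates (r = 0.841 among 2345 abundant genes). The block on footprint minus mRNA kept ribosomal proteins, glycolysis and ATF4 genes and ended the calls of lysosome and autophagy (adjusted p = 0.0802) and G2/M genes (adjusted p = 0.0907), and of the genes named here it kept only RPL22 (adjusted p = 0.0432). Ribosomal proteins were higher in 44 of 79 and lower in 8 (median 0.35, adjusted p = 2.74e-07; adjusted p = 0.0632 with an estimated correlation; 44 and 8 adjusted over the list alone), as in RPL10 (1.25), RPS21 (0.99) and RPS9 (0.85), against RPL22 (-2.43). Glycolysis genes were higher in 13 of 24 and lower in 2 (median 0.49, adjusted p = 0.000338; adjusted p = 0.228 with an estimated correlation; 13 and 2 adjusted over the list alone), as in PGAM1 (0.95), TPI1 (0.73) and GAPDH (0.64). Their rise joined higher relative footprints (median 0.18) with lower mRNA (median -0.31). ATF4 genes were higher in 13 of 31 and lower in 3 (median 0.34, adjusted p = 0.0108; adjusted p = 0.148 with an estimated correlation; 13 and 3 adjusted over the list alone), with PCK2 (0.89), PHGDH (0.84) and AARS1 (0.69). Relative footprints of the ATF4 genes had fallen (median -0.63, 0 called higher), but by less than their mRNA (median -1.12). Lysosome and autophagy genes were higher in 11 of 22 and lower in 4 (median 0.37, adjusted p = 0.0454; adjusted p = 0.288 with an estimated correlation; 11 and 4 adjusted over the list alone), with SQSTM1 (0.69) and HEXA (0.52) up and LAMP2 (-0.53) down. G2/M genes were lower in 14 of 30 and higher in 2 (median -0.32, adjusted p = 0.0198; adjusted p = 0.411 with an estimated correlation; 14 and 2 adjusted over the list alone; adjusted p = 0.074 with quantile scaling), including CKAP2 (-0.71), TTK (-0.67), KIF11 (-0.64) and TOP2A (-0.56). The remaining 19 lists were not called, with 20 higher and 9 lower of 42 MYC-responsive genes (median 0.34, adjusted p = 0.0966) and 10 higher and 6 lower of 27 glutamine genes (median 0.15, adjusted p = 0.262). Under quantile scaling camera called the MYC-responsive (adjusted p = 0.0442) and myeloid differentiation lists (0.0410) as higher. Median, mean or test differed in sign for the TCA cycle, OXPHOS, translation factors, the mitochondrial ribosome, the unfolded protein response and histones.

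By hairpin, relative efficiency of the mitochondrially encoded genes had medians of 0.81 with shBP2-1 and -0.83 with shBP2-2 (difference 1.69, adjusted p = 1.07e-44; adjusted p = 0.0371 with an estimated correlation). SLC1A5 was alike in both (0.76 and 0.72), as were MYC (0.42 and 0.37) and RPS9 (0.84 and 0.85). With shBP2-1, 788 genes were higher and 833 lower, with shBP2-2 1688 and 1708, and 57 differed between the hairpins. Median-ratio rescaling without weights turned that order around, with 2752 calls for shBP2-1, 1835 for shBP2-2 and 469 differences, and averaging the shBP2-1 footprint libraries left 385 for shBP2-1 and 23 differences. The block on footprint minus mRNA gave 779 calls for shBP2-1, 0 for shBP2-2 (2768 at unadjusted p under 0.05) and 134 between the hairpins. The shBP2-1 count was 805 or 700 without its footprint replicate 1 or 2, 2574 or 861 without its mRNA replicate 1 or 2, and 843 without shNS mRNA replicate 1. The shBP2-2 count was 1787 without its mRNA replicate 1 and 1964 without shNS mRNA replicate 1.

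The changes of the hairpins were then compared across genes, which are not independent replicates. In mRNA the log2 fold changes correlated with r = 0.619, where shared shNS libraries alone gave 0.498 in simulation, and their covariance was 0.192 against a simulated 0.0197. With both hairpins 2029 genes were higher and 1610 lower, where independent calls would give 773 and 721, and 148 genes changed in opposite directions. In relative footprints r was 0.230 (simulated 0.189) and the covariance 0.0774 (simulated 0.0182), with 100 genes higher and 68 lower under both, where independent calls would give 25.2 and 14.3, and 38 opposite. In the deposited footprints r was 0.264 (simulated 0.50) and the covariance 0.0766 (simulated 0.0872). Part of the excess overlap may come from the shared controls, which were not divided because each hairpin would have kept 1 shNS library per assay. The simulated noise was independent between genes, so it held no component shared by many genes. In mRNA the changes with shBP2-1 and shBP2-2 both followed a component that also separates replicates (r = 0.631 and 0.651 over 9188 genes). The excess over simulation therefore does not by itself show a shared effect of the knockdown.

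Footprint changes were set against mRNA changes to see how far translation followed transcript amount. Of the ATF4 genes 30 of 32 were called lower in mRNA and 23 of 31 in relative footprints, with 0 higher in either. With an estimated correlation camera called the list in footprints (adjusted p = 0.0340) but not in mRNA (0.191). Examples were ASNS at -1.03 in mRNA and -1.47 in footprints, PSAT1 at -1.17 and -0.99, and DDIT4 at -1.79 and -1.22. Across genes, which are not independent replicates, r was -0.04 in the deposited values (Spearman's rho -0.09) and -0.06 among the 2345 genes with a mean of at least 200, with footprints rescaled. Each hairpin alone gave low positive values, 0.0475 with shBP2-1 and 0.146 with shBP2-2 over 9188 genes, and 0.0976 and 0.124 among the 2345. Of 9216 genes, 123 were higher in both and 125 lower in both, where independent calls would give 150.5 and 131, and 324 were called in opposite directions. Between the hairpins the same measure was far larger, with r = 0.451 over 9188 genes and r = 0.719 among the 2345 abundant genes.

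**Figure D4:**
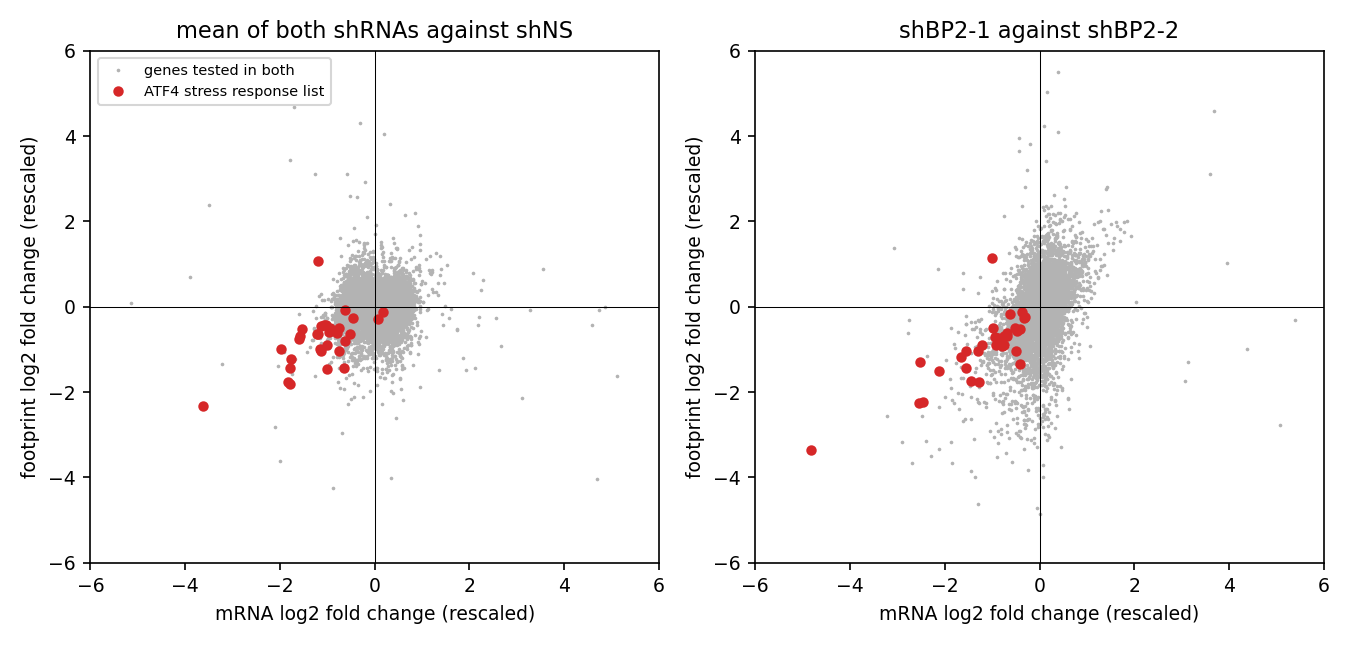
Log2 fold change of footprints (rescaled) against that of mRNA for 9216 genes, with the 31 ATF4 stress response genes marked and 2 genes outside the axes of each panel. Changes against shNS had r = -0.04 across genes, and the difference between shBP2-1 and shBP2-2 had r = 0.451.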

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

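The hairpins against IGF2BP2 differed from each other in single genes and in gene lists, but with an estimated correlation only the mtDNA-encoded genes and ribosomal proteins in relative translational efficiency held among the lists. All of the tests of explanations given here were chosen only after the results were seen. What brought these results up for a closer look was a limma or camera test of the difference between shBP2-1 and shBP2-2, and each value is shBP2-1 minus shBP2-2 on the log2 scale. In mRNA, IGF2BP2 itself was lower with shBP2-1 (-0.58), as were GPT2 (-0.85) and SLC1A5 (-0.49), while GLUL was higher (0.28). SLC1A5 also differed in relative footprints (-0.49). In all, 2981 genes differed in mRNA, 8981 in footprints and 8932 in translational efficiency as deposited, and 583 in footprints and 57 in translational efficiency after rescaling.

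Of the lists in mRNA, ATF4 genes differed most (median -0.89), followed by lower values with shBP2-1 for epithelial and fibroblast markers (-0.39), AML self-renewal (-0.27), NFkB genes (-0.25), G1/S genes (-0.20), serine and one-carbon metabolism (-0.19), glutamine metabolism (-0.18) and cholesterol synthesis (-0.14). Higher values with shBP2-1 were found for lysosome and autophagy (0.30), ribosomal proteins (0.25), G2/M genes (0.24), nuclear OXPHOS genes (0.23), the TCA cycle (0.16) and the mitochondrial ribosome (0.15). With an estimated correlation 0 of these 14 were called, and ATF4 genes came closest (adjusted p = 0.0902). In relative footprints the differences were 1.72 for mtDNA-encoded genes, -0.89 for ATF4 genes, -0.46 for replication histones, -0.45 for cholesterol synthesis, -0.38 for AML self-renewal, -0.21 for G1/S genes and for the serine list, -0.16 for the unfolded protein response, 0.11 for myeloid differentiation, -0.091 for glutamine metabolism and 0.086 for nuclear OXPHOS genes. None of the 11 held with an estimated correlation, with ATF4 genes again closest (adjusted p = 0.0617). In relative translational efficiency the differences were 1.69 for mtDNA-encoded genes, -0.27 for cholesterol synthesis and -0.21 for ribosomal proteins, and the first and last held with an estimated correlation (adjusted p = 0.0371 for both).

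The median of the ATF4 genes was lower with both hairpins and more so with shBP2-1, as in CHAC1, STC2, ASNS and SLC6A9. The list difference between the hairpins was not called with an estimated correlation in mRNA or in relative footprints. A component of the mRNA values that also separates replicates of the knockdown groups was removed by regression. The list then kept a median of -0.9912 against -1.10 before, with 32 of 32 genes below 0. These values argue against the component as the main cause of the fall in the mean of both hairpins. The component was estimated from 2 libraries per group, so its removal may be incomplete. Whether it adds to the difference between the hairpins was not tested. The median difference in mRNA was -0.8878, where no footprint library enters, so it leaves open how far the shallow shBP2-1 libraries add to the difference in footprints. Also open is whether deeper knockdown, an off-target of 1 hairpin or the state of the cultures made the hairpins differ. IGF2BP2 mRNA was lower with shBP2-1 by -0.577, and each hairpin had its own cultures, so these cannot be told apart.

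Footprint totals were lower with both hairpins and fell about as much for MYC and GLUL as for most genes. The scaling by the authors stays open. Factors were found in the values of both shNS footprint libraries but of only 1 shBP2-1 and of 0 shBP2-2 libraries, and the reads implied for that 1 library were 10.03-fold below shNS. A loss of cytosolic footprints with mitochondrial ones kept would have raised the mitochondrial share by the whole fold, but that share rose 2.138-fold with shBP2-1, against 9.69-fold for the total, and went to 0.6893 of shNS with shBP2-2. Library yield and true ribosome occupancy cannot be told apart, as no added standard of known amount is described, and the hairpins themselves differed 4.443-fold in total although IGF2BP2 was low with both.

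Changes in mRNA against shNS were weakly mirrored by footprints, with r of 0.0976 and 0.124 for each hairpin alone among abundant genes and -0.05754 for their mean. Most ATF4 genes were nevertheless called lower in each assay, 30 of 32 in mRNA and 23 of 31 in relative footprints. The mRNA list call did not hold with an estimated correlation. Counting noise in the footprints is argued against by the difference between the hairpins, which uses the shallowest libraries and still gave r = 0.7185 between mRNA and footprints over 2345 abundant genes. The mRNA changes against shNS did follow a component that also separates replicates of the knockdown groups, with r = 0.8411 among the abundant genes. Taking it out moved their correlation of the mean with footprints to 0.361. Over 9188 genes r with the component was 0.697, and taking it out moved the correlation only from -0.0353 to 0.0952. Footprint changes also followed the component, in the opposite direction (r = -0.301 among the abundant genes and -0.149 over 9188 genes). The move to 0.361 rests on that. A component confined to the mRNA libraries would leave footprints unrelated to it. A difference in mRNA library preparation or RNA quality between shNS and the knockdown libraries thus remains a candidate explanation, which the move does not favour. A translational response to the knockdown would give the same low correlation and stays open, since no other measure of mRNA is used here.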

How the results depend on the processing

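IGF2BP2 stayed lower under each alternative run in each assay, and among the genes picked by the naming rule and the later selection 930 of 992 comparisons in mRNA, 871 of 1015 in relative footprints and 1055 of 1154 in relative translational efficiency kept both direction and side of the threshold. These counts pool all alternatives, and single ones ended many more calls. The fit over all 12 libraries ended those of 27 of the 63 mRNA genes. Averaging the shBP2-1 footprint libraries ended 23 of 80 in relative footprints. The block on footprint minus mRNA ended 50 of 59 in relative efficiency. Alternatives of the relative changes and the rescaling with precision weights were chosen after seeing the data. Counts are given in the order mean of both hairpins, shBP2-1, shBP2-2 and their difference, and where no reason is given the cause was not tested. In simulated data, which varied less than the real shNS and shBP2-2 footprint libraries, the relative footprint fit gave back 48.5% of 1.5-fold changes. The alternative planned for counts, edgeR or DESeq2, was not run, because the values were rounded after scaling and are not counts. With both shBP2-1 footprint libraries left out, only the shBP2-2 comparison gives a value.

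Fitting mRNA and footprints together over all 12 libraries left 89, 71, 145 and 178 mRNA calls. Without a filter mRNA calls were 3370 for shBP2-1 and 1753 for the difference, relative footprint calls 1105 for shBP2-1, and relative efficiency calls 93 for the difference. A minimum mean of 50, which tests fewer genes, left 5875, 5875 and 5841 calls (mean, shBP2-1, difference) for deposited footprints, 5795, 5793 and 5780 for deposited efficiency, and 91 differences in relative efficiency.

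Rescaling removes the shift in footprint totals by construction. Deposited footprint calls became 442, 1485, 297 and 1849 with median ratios, 420, 1379, 296 and 1784 with quantiles, and 860, 627, 1148 and 583 with precision weights. The first 2 of these sets are also the alternatives to the weighted relative footprints. Deposited efficiency calls became 2907, 2752, 1835 and 469, then 2921, 2656, 1863 and 465, then 3355, 1621, 3396 and 57, and the relative efficiency calls moved to the same median-ratio and quantile counts for each hairpin and the difference. In efficiency, MYC reversed to 0.39, 0.46 and 0.39 under these 3 scalings, GPT2 to 0.68, 0.67 and 0.76, SLC1A5 to 0.74, 0.83 and 0.74, and GLUL to 0.16, 0.26 and 0.16. In relative footprints the chaperone gene CALR (0.19) reversed to -0.11 with quantiles.

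Footprints thinned to the smallest library gave 413 (mean) and 325 (shBP2-2) relative footprint calls and 1794 and 1331 efficiency calls. With the shBP2-1 footprint libraries averaged as 1, relative footprint calls were 221, 81 and 108 (mean, shBP2-1, difference) and efficiency calls 385 (shBP2-1) and 23 (difference).

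Lists called with an estimated correlation numbered 0 in mRNA (3 at unadjusted p under 0.05), 0 and 0 in deposited footprints and efficiency (0 at unadjusted p), 1 in relative footprints and 0 in relative efficiency (4 at unadjusted p). That alternative also rests on the few residual degrees of freedom of each fit. Fry, which does not compare a list with other genes, called 15 in mRNA, 24 and 24 in deposited footprints and efficiency, and 11 in relative efficiency. Without a trend camera called 2 lists in deposited footprints and 0 in deposited efficiency (3 at unadjusted p), and with quantiles 8 and 6. Deposited efficiency had 16 lists without a filter, 0 at a minimum mean of 50 (3 at unadjusted p) and 5 each with median ratios and with weights, and relative efficiency had 3 at that minimum.

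Agreement of the hairpins in deposited footprints (r = 0.264) was 0.191 and 0.416 with pseudocounts of 0.1 and 5, 0.577 without a filter, 0.183 with median ratios and 0.182 with quantiles. In relative footprints (0.230) it was 0.508 without a filter and 0.338 after thinning. The correlation of mRNA and footprint changes was -0.0229 at a minimum mean of 50.

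No source says that the replicate numbers pair samples across groups, and the fits used no replicate block. With the number as a block, mRNA calls were 6247, 4306, 6046 and 2180, relative footprint calls 1067 for shBP2-1 and 1086 for the difference, and relative efficiency differences 103. The replicate differences of shBP2-1 and shBP2-2 mRNA ran opposite (r = -0.833), and a crossed block gave 5305 differences in mRNA in place of 2981. Footprint minus mRNA per culture as a block, with median ratios, left 36, 779, 0 and 134 relative efficiency calls in limma (2768 at unadjusted p under 0.05 for shBP2-2), 3 relative and 5 deposited efficiency lists, and IGF2BP2 at -1.66 (adjusted p = 0.0537).

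Leaving out each library in turn gave these lowest and highest values. Calls in mRNA were 2768 to 8092, 1414 to 6999, 3676 to 7641 and 1921 to 3940, with 5 to 7 lists and r of the hairpins 0.518 to 0.667. Deposited footprint calls were 9105 to 9256, 9254 to 9269, 166 to 7973 and 8391 to 9002, with 2 to 18 lists and r 0.218 to 0.351, and RPL36A-HNRNPH2 at -0.53 to 4.99. Deposited efficiency had 0 to 9 lists (3 at unadjusted p where 0). Relative footprint calls were 254 to 1096, 93 to 820, 451 to 1521 and 110 to 898, with r 0.191 to 0.315. Relative efficiency calls were 2078 to 4058, 700 to 2574, 1787 to 3816 and 38 to 81. IGF2BP2 stayed between -2.04 and -1.97 in mRNA, -3.87 and -3.37 in relative footprints, and -1.88 and -1.37 in relative efficiency. The correlation of mRNA and footprint changes was -0.0656 to -0.0165.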

Other observations

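The topics and tests of this part were chosen only after the results were seen, except that the list comparison of the hairpins in mRNA was fixed earlier. S100A8, LYZ and MPO, picked from the myeloid differentiation list after their values were seen, differed between the hairpins. The list as a whole was not called in mRNA (adjusted p = 0.128), and its difference in relative footprints (median 0.11) was lost with an estimated correlation (adjusted p = 0.251). S100A8, a calcium-binding protein gene of monocytes and neutrophils, had mean mRNA values of 3827 in shNS, 9641 in shBP2-1 and 3206 in shBP2-2, and its relative footprints were at 1.19 with shBP2-1 and -0.15 with shBP2-2 (limma difference 1.34, adjusted p = 8.8e-07). LYZ, the lysozyme gene, went from 88450 in shNS to 144500 and 70990 in mRNA, with relative footprints at 0.71 and -0.25 (difference 0.96, adjusted p = 2.2e-07). MPO, a granule enzyme gene of earlier myeloid stages, had mRNA values of 5451, 3683 and 1626, with relative footprints at -0.07 and -1.37 (difference 1.30, adjusted p = 0.00021).

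Mitochondrially encoded genes took 6.43% of mRNA values in shBP2-1, 5.89% in shBP2-2 and 5.47% in shNS. In footprints their share was 0.630% ± 0.00474 (SD, n = 2), 0.203% ± 0.00926 and 0.295% ± 0.0395. Their summed footprints were thus 4.55-fold and 3.16-fold below shNS, closer together than the totals of all genes.

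The reads implied by the factors found in the mRNA values were 15791901 and 20511436 in shNS, and between 26848882 and 32992205 in the 4 knockdown libraries. The shNS mRNA libraries were therefore the shallowest, and their values had been scaled up. Gene length had a rank correlation of 0.373 with the mRNA change against shNS over the abundant genes, of which 98.8% had a known length. Removing length left the correlation of mRNA and footprint changes near 0 (-0.05754 before and -0.0199 after), while removing the component that separates replicates moved it to 0.361. Over 9188 genes removing the component moved it to 0.0952. Footprint changes themselves correlated negatively with the component (r = -0.301 among the abundant genes), and the move to 0.361 rests on that.

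The shBP2-1 footprint libraries differed by no more than counting noise over the 5807 genes with a sum of at least 20 (chi-square per degree of freedom 0.961), and by more than it over the 325 genes with a sum of at least 500 (1.23, chi-square p = 0.00281). After thinning to the same depth, the shBP2-2 footprint libraries gave 1.20 and the shNS footprint libraries 1.35. The shBP2-1 libraries were kept as 2 replicates, although replicates that close may have come from 1 culture. Averaged as 1 sample they left 81 genes called for shBP2-1 in relative footprints in place of 627.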
